A study of Mus musculus with 5 samples.

How the data were processed

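CD3+ T cells had been sorted, per the labels, from the ipsilateral brain hemisphere of trained and untrained mice 14 days after photothrombotic stroke. Mononuclear cells were enriched on 37% Percoll, stained for CD45 and CD3 and sorted as single cells into 384-well plates for SORT-seq. The samples were grouped by the treatment in the labels, 2 untrained and 3 trained, and cells were assigned to samples by the sample number in their names. Per the submitters' processing notes the reads were processed with Cell Ranger, with no version given. The aligner settings, the genome build, the normalisation and the integration are not given in the sources used here, so genes are placed by the chromosome in the deposited table alone.

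The deposited table is called a count matrix, but by its values each entry is a score. Its 2967 rows (2926 mouse genes and 41 spike-ins) by 692 cells ran from -2.12 to 3.74, with 72.7% of values below 0 and 0 whole numbers. In untrained sample 2 the highest value of 1335 rows equalled the square root of its cells over 30 (2.52) and 1632 rows had a mean of 0, both within 1e-06, and 0 rows did so in the other samples. This form is that of clipped residuals integrated onto 1 reference sample, which no label states. The median over genes of the SD between cells was 0.370 and 0.728 in the untrained and 0.478, 0.515 and 0.429 in the trained samples. The table gives no counts, so the depth per sample is unknown and no precision from depth could be given. A second table of 384 columns headed by barcodes differed from the first 384 columns of the main one by at most 5.0e-10 and was not used.

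A count test on summed molecules per sample, cell filters by molecules and gates by detected molecules had been planned. The values do not allow them, so the mean score per gene was taken over the cells of each sample and class and fitted with limma (3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The model had training as its term in all sorted cells, T cell-like cells, CD8-gated cells and CD4-gated cells. The classes were compared with sample as a block, and the interaction of class and training was added for the difference between classes, with Cd4, Cd8a and Cd8b1 left out of both. All tests were two-sided unless a one-sided test is named. The comparisons, the gene lists, the cell type markers, the rule for named genes and the first set of other settings were fixed before the data were examined. The gates by score, the pooling of T cell-like clusters, limma on mean scores and the alternatives named as added were chosen after the data were seen.

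CD8-gated cells had a mean score of Cd8a and Cd8b1 above 0 and Cd4 at or below 0, and CD4-gated cells the reverse. A gate on a score is a range, not a detected transcript. Of the CD8-gated cells (23% of the 692 cells) 50 had a gate score between 0 and 0.25, and of the CD4-gated cells (21.1%) 34 did. The medians over CD8-gated cells were 0.704 for Cd8a, 0.391 for Cd8b1, -0.368 for Cd4, 0.199 for Cd3e and -0.314 for Cst3. Over CD4-gated cells they were 0.794 for Cd4, -0.297 for Cd8a, -0.322 for Cd8b1, 0.090 for Cd3e and -0.232 for Cst3. The other T cell markers had medians on both sides of 0. In CD8-gated cells Cd3d, Lck and Thy1 lay at 0.089, 0.206 and 0.255. There Cd3g, Cd2 and Cd247 lay at -0.133, -0.158 and -0.174. In CD4-gated cells Lck and Thy1 lay at 0.093 and 0.148. There Cd3d, Cd3g, Cd2 and Cd247 lay at -0.17, -0.103, -0.135 and -0.112. A total of 57 cells lay above 0 for both gates and 330 for neither. The planned minimum of 20 cells per class and sample was missed by trained sample 1 (17 CD8-gated and 16 CD4-gated cells), and the classes were tested all the same. Clusters came from 20 principal components, 15 neighbours and Leiden at a resolution of 0.8 (leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 in Python 3.11.15), which gave 7 clusters. No cluster had 20 cells in every sample, so clusters were tested for training only as the pooled T cell-like clusters.

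Of the fixed gene lists 19 had at least 3 measured members and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The type 17 list had 2 measured members (Maf and Stat3) and the trophic and repair list 1 (Lgals1), and neither was tested. Named genes were, for each comparison and direction, up to 10 past the threshold with the largest difference whose groups did not overlap, or the 5 with the smallest p where fewer than 5 passed, up to 3 members of each list with the smallest p, and a set of lineage genes fixed in advance. Foxp3, Gzmb, Gzmk, Ifng, Mki67, Trac, Trbc1, Trdc and Cx3cr1 were not analysed here. Some genes that the rule names are not reported here. Shares of cells were compared by two-sided exact permutation over all 10 splits of 2 and 3 samples, where the smallest possible p is 0.1, with 95% Wilson intervals per sample and 3 counts as the limit behind a count of 0. The fits were tested on simulated data, in which score differences of known size were added to 200 genes of the trained samples.

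Alternatives were leaving out each sample in turn, T cell-like cells only, leaving out ribosomal and mitochondrial genes, other list tests and other Leiden resolutions (0.5 and 1.2). Added after the data were seen were a gate at 0.25, gated cells of T cell-like clusters only, leaving out cluster 7, scores divided by their SD between cells and samples weighted by their cells. Figures were drawn with matplotlib 3.10.9.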

Results

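Single CD3+ T cells were profiled from the brains of wildtype C57BL/6 mice 14 days after a photothrombotic stroke, a cortical infarct made by light activation of a dye in the blood. Trained mice had run on wheels from day 2 after the stroke, and untrained mice had not. The 5 samples, 2 untrained and 3 trained, were each read from wells of a 384-well plate by SORT-seq, in which every well holds 1 sorted cell and its own barcode. The deposited table held scores of 2926 mouse genes and 41 spike-in RNAs in 692 cells. Untrained samples 1 and 2 gave 144 and 190 cells, or 37.5% (95% Wilson interval 32.8 to 42.4) and 49.5% (44.5 to 54.5) of their wells. Trained samples 1, 2 and 3 gave cells in 17.2% (13.7 to 21.3), 32.3% (27.8 to 37.1) and 43.8% (38.9 to 48.8) of their 384 wells, which is 66 cells in sample 1 and 168 in sample 3. The mean share was 43.5% of wells in untrained and 31.1% in trained samples (two-sided exact permutation p = 0.4 over 10 splits). The depth of each sample is unknown because the table holds no counts. All differences below are differences of deposited scores, which by their form may be batch-integrated, not of expression levels. The labels do not say that the plates came from separate animals, so the p-values measure only the spread between these samples.

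Of 692 cells 383 lay in clusters with positive T cell marker scores, and 34 in a cluster led by genes that include lysosomal proteases and a complement gene. Clusters 1, 2 and 3 had positive mean scores of 7 T cell markers (0.353, 0.520 and 0.13) and made up the 383 T cell-like cells. Cluster 1 (19.5% of the 692 cells) was led by Rps24 and Rpsa of the small ribosomal subunit and by Rpl12 of the large one. Cluster 2 (18.6%) was led by Ms4a4b, the actin gene Actb, the mitochondrial oxidase gene mtCo1, the stem cell antigen gene Ly6a and the T cell surface gene Thy1. Cluster 3 (17.2%) was led by the thymosin gene Tmsb4x, the galectin gene Lgals1 and Lat, the adaptor of T cell receptor signalling. Cd3e, a chain of the T cell receptor complex, had mean scores of 0.430, 0.576 and 0.176 in clusters 1 to 3.

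The other clusters had negative T cell marker scores and were not named. Every fixed gene list also had a negative mean score in clusters 4, 5 and 6, among them ribosomal protein genes (-0.531, -0.266 and -0.699). Clusters 1, 2 and 3 were also positive for the 2 measured oligodendrocyte markers (0.234, 0.295 and 0.07). The sign of the T cell marker score therefore does not tell T cells from other cells in these clusters. Cluster 4 (16.9% of cells) and cluster 6 (64 cells, 9.25%) were led by the noncoding RNAs A630089N07Rik (mean scores 1.87 and 2.44) and Kcnq1ot1 (1.77 and 2.44). Cluster 5 (94 cells) had no gene with a high mean score, and its leading gene Tmem258 had a mean of 0.216. Cluster 7 (34 cells) was led by the protease inhibitor gene Cst3 (2.46), the lysosomal protease genes Ctsd (2.34), Ctss (2.28) and Ctsb (2.03), the complement gene C1qb (2.29), the adaptor gene Tyrobp (1.94) and the apolipoprotein gene Apoe (1.72). The fixed marker lists had 1 measured gene for microglia and 3 for macrophages or monocytes, too few to name cluster 7.

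The shares of T cell-like cells and of the other clusters were compared between trained and untrained samples to ask whether training altered which cells lay in the injured brain. T cell-like cells made up 60.4% ± 4.44 (SD, n = 3) of cells in trained and 52.1% ± 11.8 (SD, n = 2) in untrained samples. CD8-gated cells, with a positive mean score of Cd8a and Cd8b1 and no positive score of Cd4, made up 25.7% ± 1.81 and 20.9% ± 5.77. CD4-gated cells, gated the other way round, made up 24.0% ± 6.69 and 19.5% ± 6.77. None of the 12 differences of shares tested passed, with the smallest two-sided exact permutation p = 0.2 for CD8-gated cells (adjusted p = 0.982), where 10 splits allow no p below 0.1. Cluster 7 held 30 of 190 cells of untrained sample 2 (15.8%, Wilson interval 11.3 to 21.6) and 0 of 144 cells of untrained sample 1, a count that allows a share of up to 2.08%. It held 3 cells of trained sample 1, 1 of trained sample 2 and 0 of 168 cells of trained sample 3, which allows up to 1.79%. These intervals and limits cover counting error only. Without untrained sample 2 the difference in T cell-like cells was -0.021 points, that in CD4-gated cells -0.256 points and that in cluster 7 1.78 points. Without untrained sample 1 the differences in clusters 3, 4, 5 and 6 and in cells above 0 for both gates changed sign, to 6.99, -2.18, 2.80, -3.33 and 5.39 points.

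**Figure D1:**
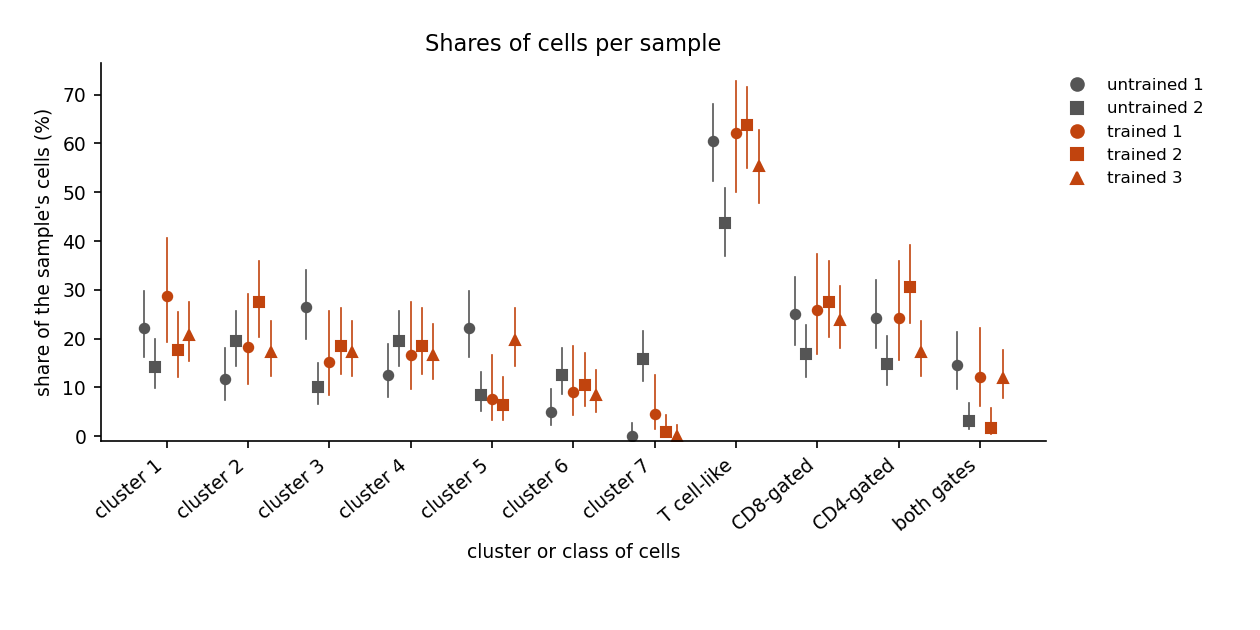
Share of each sample's cells (%) in the 7 clusters, in the T cell-like clusters together and in the gated classes, with 95% Wilson intervals as lines, untrained samples in grey and trained samples in red. Cluster 7 stands at 15.8% in untrained sample 2 and at 4.55% or less in the other samples.

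CD8-gated and CD4-gated cells of the same sample were compared to describe the T cell classes in the brain after stroke. Of the 5 genes that passed, 4 were higher in the CD8-gated cells, and with scores divided by their SD 53 passed, 18 higher and 35 lower. Nkg7, which codes for a membrane protein of cytotoxic granules, had a mean score of 0.496 in CD8-gated and -0.027 in CD4-gated cells, a difference of 0.523 ± 0.071 (SE, limma adjusted p = 0.00653). The chemokine gene Ccl5 was higher by 0.659 ± 0.104 (adjusted p = 0.0131), Ctsw, a cathepsin of cytotoxic lymphocytes, by 0.394 ± 0.063 (adjusted p = 0.0131), and Ly6c2, the surface antigen Ly6C, by 0.409 ± 0.067 (adjusted p = 0.0133). Each of these was higher in CD8-gated cells of 5 of 5 samples. Ctsb, the lysosomal protease cathepsin B, was lower in CD8-gated cells of every sample, with means of -0.241 and 0.157 and a difference of -0.397 ± 0.074 (adjusted p = 0.043). In the deposited table these genes lie on chromosomes 7, 11, 19, 15 and 14.

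**Figure D2:**
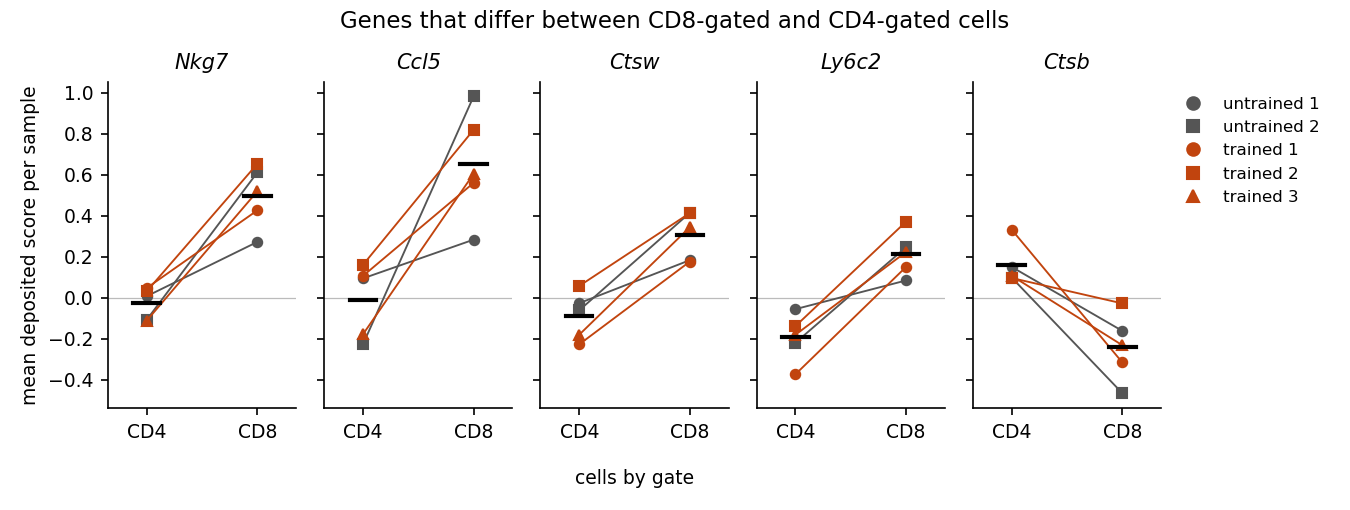
Mean deposited score per sample in CD4-gated and CD8-gated cells for the 5 genes past the limma threshold, with lines joining the classes of 1 sample and black bars for the mean of 5 samples. Nkg7, Ccl5, Ctsw and Ly6c2 were higher in CD8-gated cells and Ctsb was lower, in every sample.

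These were the 5 of 2923 genes that passed limma at an adjusted p under 0.05, and 383 genes had an unadjusted p under 0.05 (29% of them higher, 71% lower in CD8-gated cells), where chance gives 146.2. The sign was the same in all 5 samples for 404 genes (13.8%), where chance gives 6.25%. Among genes with differences that did not pass, Xcl1, a chemokine for dendritic cells, differed by 0.340 ± 0.076 and Eomes, a transcription factor of cytotoxic cells, by 0.237 ± 0.065. Cxcr6, a chemokine receptor of tissue T cells, differed by 0.246 ± 0.068, and the ribosomal gene Rpl32 by 0.340 ± 0.065 (adjusted p = 0.0505). On the CD4 side lay the transcription factor gene Maf (-0.373 ± 0.078), the costimulatory receptor gene Icos (-0.275 ± 0.061), Cd44 (-0.266 ± 0.063) and the neuropilin gene Nrp1 (-0.269 ± 0.071). With scores divided by their SD, Maf (adjusted p = 0.000472), Icos, Cd44, Nrp1, Xcl1, Eomes and Rpl32 passed. Cd3e differed by 0.104 ± 0.065 and Tcf7, a transcription factor of naive and memory T cells, by -0.019 ± 0.062, neither past the threshold. Foxp3, Gzmb, Gzmk and Ifng were not analysed here. Of the CD4-gated cells, 21.1% of all 692 cells, 8 lay in cluster 7, against 1 of the CD8-gated cells, 23% of all cells. The classes also lay in different T cell-like clusters, with 56, 37 and 24 CD8-gated and 21, 46 and 40 CD4-gated cells in clusters 1, 2 and 3. With gated cells of the T cell-like clusters only, 4 genes passed, 3 of them among the 5 (Nkg7, Ctsw and Ly6c2), and the difference of Ctsb was -0.311 (adjusted p = 0.0758). Without trained sample 1, which had 17 CD8-gated and 16 CD4-gated cells, 0 genes passed (smallest limma adjusted p = 0.0822, differences of Nkg7 0.560, Ccl5 0.710, Ctsw 0.392, Ly6c2 0.380 and Ctsb -0.334). Without trained sample 2 the genes past the threshold were Ctsb and Nkg7, without trained sample 3 they were Ccl5 and Nkg7, and without either untrained sample Ctsb did not pass (adjusted p = 0.0508 and 0.106). With a gate at 0.25, 6 genes passed, 4 of them among the 5, and Ctsb was at -0.330 (adjusted p = 0.072). With samples weighted by their cells 4 passed and Ctsb was at -0.360 (adjusted p = 0.0575).

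In the same comparison 8 of 19 fixed gene lists passed camera with a preset correlation of 0.01, and 0 passed with an estimated correlation. Cytotoxic effector genes were higher in CD8-gated cells for 11 of 14 measured members (mean difference 0.192, camera adjusted p = 9.5e-10, adjusted p = 0.188 with an estimated correlation). Of these 14 genes 3 passed over all genes and 11 when adjusted over the list alone, 9 of them higher. The fixed list held 27 genes, and the 14 measured ones did not include Gzmb, Gzmk or Ifng. Ribosomal protein genes were higher for 64 of 67 members (mean 0.133, camera adjusted p = 1.61e-26, adjusted p = 0.581 with an estimated correlation), with 0 past limma over all genes and 12 adjusted over the list alone. This list had mean scores of 0.717, 0.433 and 0.167 in clusters 1, 2 and 3, and interferon-stimulated genes -0.044, 0.273 and -0.029. The type 1 helper list had 7 members higher and 7 lower, with a median of 0 and a mean of 0.103 (camera adjusted p = 0.00221, adjusted p = 0.688 with an estimated correlation). Its 3 members past the threshold over all genes were Nkg7, Ccl5 and Ly6c2, which are also expressed by cytotoxic cells, and 5 passed adjusted over the list alone. Nuclear genes of oxidative phosphorylation were higher for 44 of 70 members by a mean of 0.018 (camera adjusted p = 0.00221, adjusted p = 0.719 with an estimated correlation), with 0 past either adjustment of the limma p.

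Lists with lower scores in CD8-gated cells covered interferon, regulatory and stress genes. Regulatory T cell program genes were lower for 9 of 10 members (mean -0.169, camera adjusted p = 0.000232, adjusted p = 0.581 with an estimated correlation), among them Maf, Icos and Nrp1. Adjusted over the list alone 9 of these genes passed, 1 of them higher, and 0 passed limma over all genes. The fixed list held 29 genes, and the 10 measured ones did not include Foxp3, Il2ra or Ctla4. Interferon-stimulated genes were lower for 31 of 41 members (mean -0.106, camera adjusted p = 0.00025, adjusted p = 0.581 with an estimated correlation), with 6 past the threshold adjusted over the list alone and 0 over all genes. The interferon-inducible genes Ly6a and Slfn5 differed by -0.431 ± 0.091 and -0.343 ± 0.075. Heat shock and dissociation stress genes were lower for 18 of 22 members (mean -0.113, camera adjusted p = 0.00201, adjusted p = 0.725 with an estimated correlation), among them Junb (-0.304), with 9 past the threshold adjusted over the list alone. Glucocorticoid response genes were lower for 11 of 13 members (mean -0.113, camera adjusted p = 0.0126, adjusted p = 0.725 with an estimated correlation), with 4 past it adjusted over the list alone. The remaining 11 lists did not pass camera. With a gate at 0.25 the camera adjusted p was 0.0933 for the stress list and 0.0681 for the glucocorticoid list, and without trained sample 1 it was 0.078 for the latter. By fry, which asks whether the genes of a list move on balance 1 way, 0 lists passed, and by its mixed test 5 did.

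**Figure D3:**
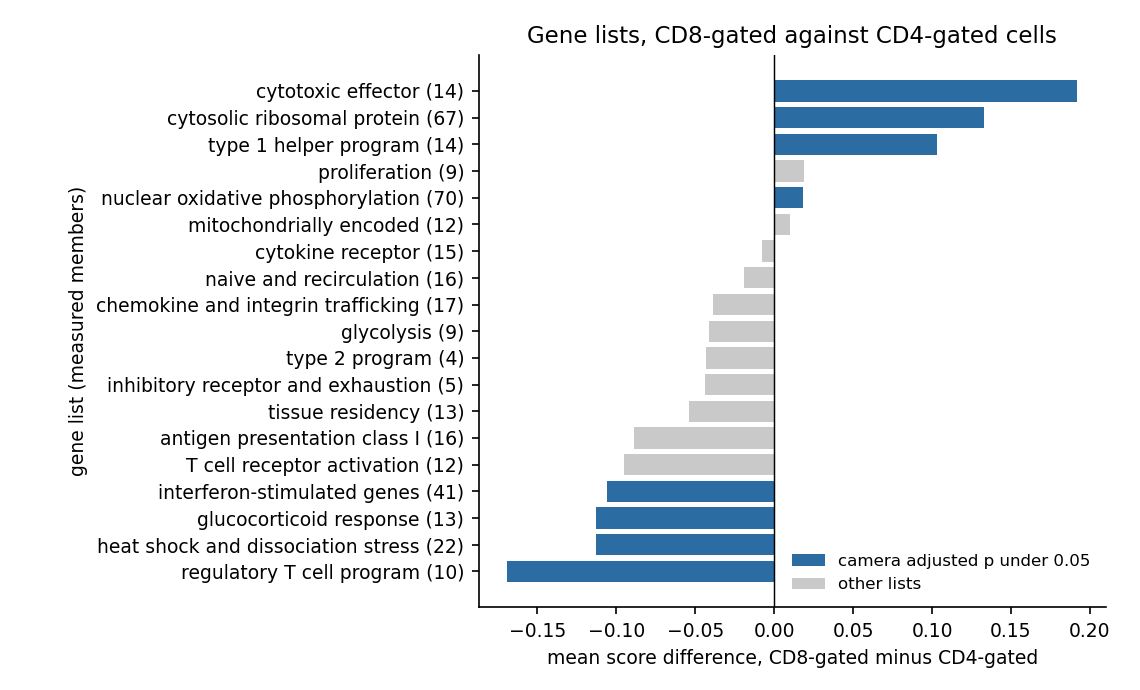
Mean score difference of each tested gene list, CD8-gated minus CD4-gated cells over 5 samples, with lists past the camera threshold at the preset correlation in blue. The cytotoxic effector list stands at 0.192 and the regulatory T cell program list at -0.169, and 0 lists passed with an estimated correlation.

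In all sorted cells, trained and untrained samples were compared to ask what training altered in the cells sorted as T cells. None of the genes with the smallest p passed the threshold. Sept6, which codes for a septin of the cytoskeleton, had a mean of 0.092 ± 0.006 (SD, n = 3) in trained and -0.043 ± 0.014 (SD, n = 2) in untrained samples, a difference of 0.135 ± 0.022 (SE, limma adjusted p = 0.203). Differences of the scaffold gene Ahnak (0.099), the small GTPase gene Arl4c (0.109), the myosin light chain gene Myl12a (0.107) and the protease inhibitor gene Ctla2a (0.098) had adjusted p between 0.317 and 0.318. The lysosomal genes Ctsd (-0.154), Ctsb (-0.12) and Grn (-0.149), the kinase gene Sgk1 (-0.134), a glucocorticoid target, and Lgals3bp (-0.103), an interferon-inducible gene, each had an adjusted p of 0.317. Cluster 7, with mean scores of 2.34 for Ctsd and 2.03 for Ctsb, held 15.8% of the cells of untrained sample 2. Without cluster 7 the differences of Ctsd and Ctsb were 0.023 and 0.025. Many gene means of untrained sample 2 were 0 with these cells included, so leaving them out may itself lower its means. No cell of untrained sample 1 or trained sample 3 lay in cluster 7. Their means were -0.04 and -0.164 for Ctsd and 0.006 and -0.091 for Ctsb. Without untrained sample 2 the differences of Ctsd and Grn were -0.109 and -0.088. How far cluster 7 made these differences cannot be told.

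By limma 0 of 2926 genes passed in all sorted cells, and 7.72% of them had an unadjusted p under 0.05 where chance gives 5%, 47.8% of these higher and 52.2% lower in trained samples. This share was 10.3% without untrained sample 1 (59.5% higher), and without untrained sample 2 it was 2.97% (58.6% higher). In untrained sample 2 the mean over all cells was 0 within 1e-06 for 1632 of the 2967 genes and spike-ins, as if centred on that sample, so the p-values and the simulated recovery in all sorted cells may rest partly on fixed values. Without untrained sample 1, 3 genes passed, among them Ctsd (-0.199) and Grn (-0.209). Ribosomal protein genes had a mean difference of 0.024, with 49 of 67 members higher (camera adjusted p = 0.00578, adjusted p = 0.868 with an estimated correlation). Without untrained sample 2 their mean was -0.009 (camera adjusted p = 0.789), without trained sample 1 it was 0.008 (adjusted p = 0.588), without untrained sample 1 it was 0.057, and in the T cell-like cells alone it was -0.081. Heat shock and dissociation stress genes had a mean of -0.024, with 15 of 22 members lower (camera adjusted p = 0.0355, adjusted p = 0.868 with an estimated correlation). Their mean was 0.020 without cluster 7, and ran from -0.033 to -0.018 with each sample left out in turn. Leaving out untrained sample 2 left 0 lists past camera, and leaving out trained sample 2 or 3 left 1. The other 17 lists did not pass camera, 0 passed fry, and 2 passed its mixed test (chemokine and integrin trafficking, adjusted p = 0.0227, and the regulatory T cell program, adjusted p = 0.0467). Adjusted over the list alone, 1 of 41 interferon-stimulated genes passed (Lgals3bp), 2 of 14 cytotoxic effector genes (Lamp1, a lysosomal membrane protein, at -0.118, and Nkg7 at 0.085), 1 of 13 tissue residency genes (Rgs2, -0.110) and 1 of 12 T cell receptor activation genes (Egr1, -0.101). The interleukin 2 receptor gene Il2rb (0.111) passed in both the regulatory T cell and the cytokine receptor list, and Sgk1 in the glucocorticoid list. Without cluster 7 the differences of Lamp1, Rgs2 and Egr1 were 0.003, 0.015 and 0.024. Untrained sample 1 and trained sample 3 had no cell in cluster 7. Their means were -0.059 and -0.146 for Lamp1, -0.028 and -0.107 for Rgs2 and -0.131 and -0.213 for Egr1.

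**Figure D4:**
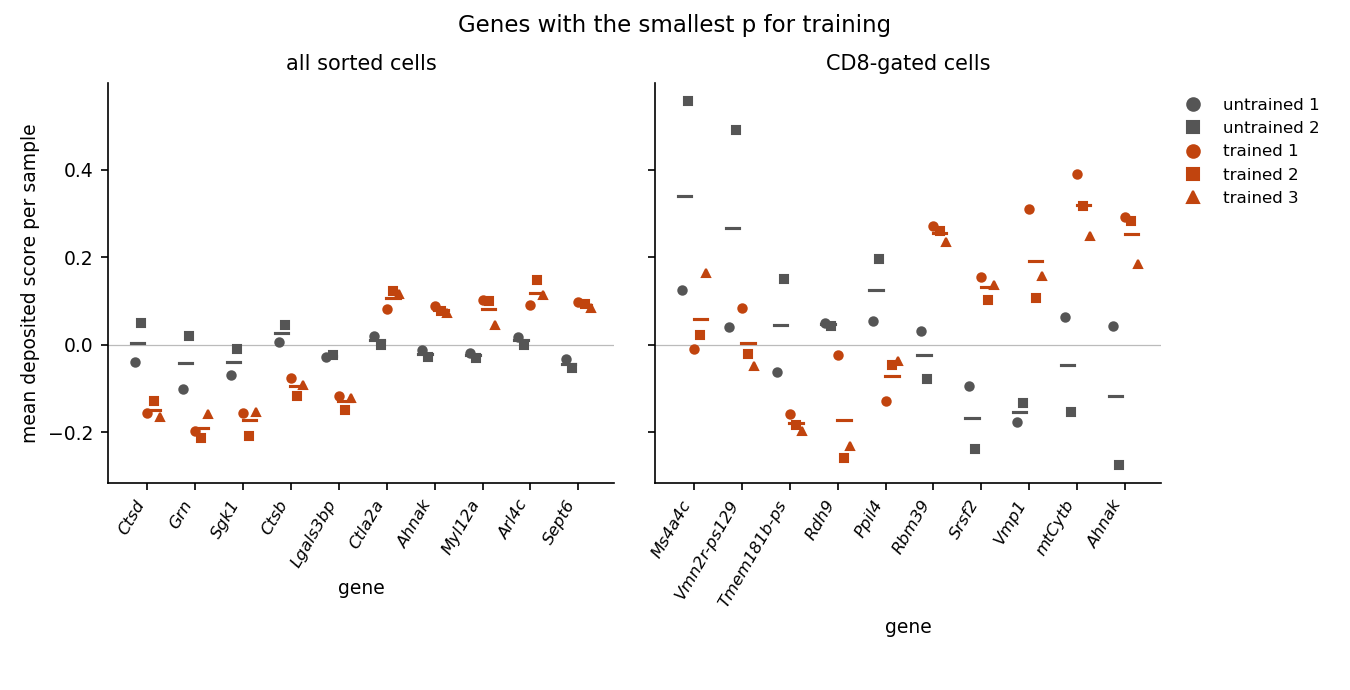
Mean deposited score per sample, in all sorted cells and in CD8-gated cells, of the 10 genes with the smallest limma p (5 of each direction), with short lines for group means, untrained samples in grey and trained samples in red. None of these genes passed the threshold, with adjusted p of 0.203 or more in all sorted cells and 0.261 or more in CD8-gated cells.

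In the T cell-like cells, ribosomal protein genes had lower scores in trained samples. Of 67 members 62 were lower, with a mean difference of -0.081 (camera adjusted p = 1.11e-07, adjusted p = 0.969 with an estimated correlation), and 0 passed limma over all genes or adjusted over the list alone. Rpl3 differed by -0.179 ± 0.054 and Rpl11 by -0.212 ± 0.068 (SE, limma adjusted p = 1 for each). The direction rested on untrained sample 2, since without it the list's mean was 0.046 (camera adjusted p = 0.00141), and without untrained sample 1 it was -0.208. Beyond the ribosome, the lowest p among genes lower in trained samples belonged to Pa2g4, a growth-related RNA-binding protein (-0.167 ± 0.036), Rab14, a GTPase of vesicle traffic (-0.139), and the calmodulin gene Calm3 (-0.13). On the higher side were Tmem258 (0.127), the proteasome gene Psmb5 (0.13), the transcription kinase gene Cdk9 (0.149), the splicing factor gene Srsf2 (0.111) and Arl4c (0.153). The interferon-stimulated genes Irf7 and Isg15 differed by -0.114 and -0.094. By limma 0 of 2926 genes passed and 60 (2.05%) had an unadjusted p under 0.05 (24 higher, 36 lower), with 17.9% of genes without untrained sample 1 (23.4% of them higher), 3.55% without untrained sample 2 (86.5% higher), and 34, 31 and 38 genes without trained samples 1, 2 and 3. The groups lay apart for 14.7% of genes, where chance gives 20%. Without untrained sample 1, 122 genes and 4 lists passed, the genes including Rpl3 (-0.260, limma adjusted p = 0.0175), Rpl11 (-0.330, adjusted p = 0.00796) and Cdk9 (0.208). Without untrained sample 2 Rpl3 and Rpl11 were at -0.097 and -0.094, and 0 genes and 2 lists passed.

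In CD8-gated cells, differences with small p lay mostly on the higher side in trained samples, and none passed the threshold. The mitochondrial cytochrome gene mtCytb had a mean of 0.319 ± 0.072 (SD, n = 3) in trained and -0.045 ± 0.153 (SD, n = 2) in untrained samples, a difference of 0.364 ± 0.082 (SE, limma adjusted p = 0.261). The autophagy gene Vmp1 differed by 0.347 ± 0.080 and Ahnak by 0.370 ± 0.087 (adjusted p = 0.261 for each), and the splicing genes Srsf2 and Rbm39 by 0.298 and 0.279 (adjusted p = 0.5 for each). Il2rb (0.263), the phosphatase gene Dusp2 (0.288), the chaperone gene Calr (0.263) and Tnfrsf18 (0.240), which codes for the costimulatory receptor GITR, also lay on the higher side. On the lower side lay Ms4a4c (-0.282), Ppil4 (-0.196), the retinol dehydrogenase gene Rdh9 (-0.218) and the pseudogenes Tmem181b-ps (-0.224) and Vmn2r-ps129 (-0.261). The cytotoxic genes Xcl1, Id2 and Tbx21 differed by 0.230, 0.176 and 0.14.

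By limma 0 of 2926 genes passed in CD8-gated cells, and 8.92% of them had an unadjusted p under 0.05 where chance gives 5%, with 32 genes lower and the other 87.7% higher. This share was 16.9% without untrained sample 1, 2.94% without untrained sample 2 and 4.92% without trained sample 2, with 79.4%, 95.3% and 86.8% of these genes higher. The groups lay apart for 25.1% of genes, where chance gives 20%. Mitochondrially encoded genes were higher for 11 of 12 members (mean 0.125, camera adjusted p = 0.0877) and 0 of 19 lists passed camera. Adjusted over the list alone, mtCytb passed in the mitochondrial list, Dusp2 in the T cell receptor activation list, Il2rb and Tnfrsf18 in the regulatory T cell list, Il2rb in the cytokine receptor list and Calr in the class I antigen presentation list. T cell-like cells made up 66.7% and 59.4% of the CD8-gated cells of the untrained samples and 82.4%, 85.3% and 77.5% of those of the trained samples. With gated T cell-like cells only, the small p were 68 higher and 73 lower, and the mean of the mitochondrial list was -0.026. Without untrained sample 1, 3 lists passed camera, among them the mitochondrial list (mean 0.192, adjusted p = 0.0163), without untrained sample 2, where its mean was 0.059, 3 lists passed, and without trained sample 1, 1.

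In CD4-gated cells, the smallest p belonged to Top2b and Rab14, with lower scores in trained samples, and none passed the threshold. Top2b, a DNA topoisomerase, had a mean of 0.072 ± 0.098 (SD, n = 3) in trained and 0.416 ± 0.113 (SD, n = 2) in untrained samples, a difference of -0.343 ± 0.093 (SE, limma adjusted p = 0.999). Rab14 (-0.339), Rpl11 (-0.309), the RNA-binding protein gene Hnrnpa3 (-0.291) and 6820431F20Rik (-0.321) lay on the same side, and the LIM protein gene Crip1 (0.280), Tmem258 (0.253), the cytokine gene Flt3l (0.229), Ubac2 (0.202) and the ubiquitin enzyme gene Cdc34 (0.236) on the other. Interferon-stimulated genes were lower for 33 of 41 members (mean -0.074, camera adjusted p = 0.192), and 0 of 19 lists passed camera. Slfn1 of this list differed by -0.206, and by 0.027 without untrained sample 2. By limma 0 of 2926 genes passed and 71 (2.43%) had an unadjusted p under 0.05 (12 higher, 59 lower), with 17.7% of genes without untrained sample 1 (8.3% of them higher), 15 genes without untrained sample 2 (12 higher, 3 lower), and 33 and 34 genes without trained samples 2 and 3. The groups lay apart for 14.5% of genes, where chance gives 20%. Without untrained sample 1, 8 genes and 3 lists passed, and without trained sample 1 or 3, 0 genes and 2 lists.

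Whether training differed between the classes was tested by the interaction of training and class. The score of CD8-gated minus that of CD4-gated cells lay higher in trained samples for the RNA-binding protein gene Hnrnpa3 (0.156 in trained and -0.315 in untrained samples, interaction 0.471 ± 0.129), for Top2b (0.089 and -0.419, interaction 0.508 ± 0.145), for Mat2a, which makes the methyl donor of the cell (0.438), for the kinase gene Riok1 (0.398) and for the transcription factor gene Klf13 (0.512), and none passed (limma adjusted p = 0.758 for each). The mitochondrial gene mtAtp6 (0.414), the interferon-inducible GTPase gene Gbp2 (0.383) and Dusp2 (0.357) were on the same side, and Mdn1 (-0.331), a ribosome assembly gene, on the other. By limma 0 of 2923 genes passed, 168 higher and 5 lower genes (5.92%) had an unadjusted p under 0.05, against 20.7% of genes without untrained sample 1, 0.75% without untrained sample 2 and 3.83% without trained sample 2, and the groups lay apart for 20.8% of genes, where chance gives 20%. Camera gave 0 of 19 lists, led by the type 1 helper list (13 of 14 members higher, mean 0.160, adjusted p = 0.191). With gated T cell-like cells only, 68.9% of the small p were higher, against 97.1% with all gated cells. Without untrained sample 1, 10 genes passed, among them Klf13 at 0.871 (limma adjusted p = 0.0456), without untrained sample 2 Klf13 was at 0.152 and 3 lists passed, and without trained sample 1 or 3, 1 list.

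Simulated changes show which sizes of score difference these tests could find. They were set as differences of scores, so they do not show what an integration before deposit may have removed between the groups. The recovery below thus does not give the power to find a difference in expression. A score difference of 0.2 added to 200 genes was found in 92.5% of them in all sorted cells and in 47% in the T cell-like cells. In CD8-gated and CD4-gated cells a difference of 0.4 was found in 75.5% and 48%, and one of 0.2 in 0% of genes. For the interaction a difference of 0.8 was found in 86.5% and one of 0.4 in 0%. A difference of 0.1 was found in 38% in all sorted cells and in 0% in the T cell-like and the gated cells.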

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

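Leaving out cluster 7, gating at 0.25, using only gated cells of the T cell-like clusters, testing the lists in T cell-like cells only, dividing scores by their SD and weighting samples by their cells were settings chosen after the data were seen. Where a sample was left out and 1 untrained sample stayed, that lone sample is assumed to vary like the trained ones. In all sorted cells, with only T cell-like clusters, the differences of Ctsd (0.097), Ctsb (0.073), Grn (0.059), Lamp1 (0.031), Rgs2 (0.015), Egr1 (0.052), Rpl12 (-0.018), Junb (0.004) and Cd3e (-0.011) were reversed, as were the ribosomal list (-0.081) and the heat shock list (0.013), and 1 list passed camera in place of 2. Without cluster 7, Ctsd (0.023), Ctsb (0.025), Lamp1 (0.003), Rgs2 (0.015), Egr1 (0.024), Junb (0.013) and the heat shock list (0.020) were reversed and 0 lists passed. Without untrained sample 2, which held 30 of the 34 cells of cluster 7, Ctsd (-0.109) and Grn (-0.088) kept their direction. With an estimated correlation, and by the directional test of fry, 0 lists passed in all sorted cells (2 with the preset correlation), in T cell-like cells (1) and between CD8-gated and CD4-gated cells (8). With gated T cell-like cells only, 1 list passed for training in CD8-gated cells and 1 for the interaction, the same numbers as with a gate at 0.25, and the mitochondrial list was at -0.026 in CD8-gated cells of the first setting. Between the gated classes 53 genes passed with scores divided by their SD (18 higher, 35 lower), among them all 5 of the report. This scaling moved the share of genes with an unadjusted p under 0.05 that were higher in trained samples from 47.8% to 34.6% in all sorted cells, from 40% to 50.6% in T cell-like cells and from 16.9% to 30% in CD4-gated cells. Leaving out each sample in turn gave 0 to 3 genes in all sorted cells, 0 to 122 in T cell-like cells, 0 to 8 in CD4-gated cells, 0 to 10 for the interaction and 0 to 7 between the classes. Lists past camera numbered 0 to 3 in all sorted cells, 1 to 4 in T cell-like cells, 0 to 3 in CD4-gated cells, 0 to 3 in CD8-gated cells and 0 to 3 for the interaction. The ribosomal list ran from -0.009 to 0.057 in all sorted cells and from -0.208 to 0.046 in T cell-like cells. In CD4-gated cells Slfn1 ran from -0.438 to 0.027, and Tcf7 between the classes from -0.054 to 0.023. Differences of shares, in points, ran from -9.40 to 6.99 for cluster 3, -2.18 to 4.79 for cluster 4, -11.0 to 2.80 for cluster 5, -3.33 to 4.44 for cluster 6 and -14.0 to 1.78 for cluster 7. They ran from -0.021 to 16.7 for T cell-like cells, -0.256 to 9.31 for CD4-gated cells and -6.04 to 5.39 for cells above 0 for both gates. For these changes the cause was not tested. The other counts of genes and lists, taken as unchanged where equal or close, and the other shares were unchanged in 99 comparisons under the settings fixed in advance and in 38 under the added ones. Among single genes and single lists, 586 and 399 kept their direction and their side of the threshold. Another 40 and 7 lost their call in the same direction, 11 and 12 gained one, and 13 and 10 were reversed. Results past the threshold in neither setting count as kept if their direction stayed. Where only the list test was changed, the direction could not change. The kept numbers were thus partly fixed in advance and do not measure robustness. Not run, for want of counts, were another count test and its normalisation, library size alone, a low-count filter, cell filters at 1000 molecules or none, thinned cells and the comparison of depth and quality. Depth is unknown, so its effect on these results could not be measured.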

Other observations

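Within the T cell-like cells of each sample, genes of some programs varied together from cell to cell. The measure was the mean pairwise correlation of a list's members, after each gene's linear fit on the cell's mean score over all mouse genes was taken out. Interferon-stimulated genes, which respond to type I and type II interferon, had means of 0.176 to 0.279 over the 5 samples. Mitochondrially encoded genes had means of 0.311 to 0.401 and ribosomal protein genes 0.201 to 0.362. Weaker correlations joined the genes of class I antigen presentation (0.062 to 0.096), of naive and recirculating T cells (0.048 to 0.072) and of cytotoxic effectors (0.039 to 0.077). Each of these 6 lists lay at or above the 95th percentile of 1000 random lists with matched SD in 5 of 5 samples. So did the nuclear oxidative phosphorylation list (0.012 to 0.034) and the heat shock and dissociation stress list (0.019 to 0.036), so correlations near 0 can reach this percentile. The inhibitory receptor and exhaustion list and the cytokine receptor list reached it in 0 of 5 samples.

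The correlation was compared between trained and untrained samples for 18 lists, by two-sided exact permutation over 10 splits, without adjustment. Type 1 helper genes had a mean of 0.067 in trained and 0.027 in untrained samples, and T cell receptor activation genes 0.035 and 0.056 (exact permutation p = 0.1 for each, the smallest these splits can give). Interferon-stimulated genes had means of 0.217 and 0.186 (exact permutation p = 0.9).

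Of the tests below, those of doublets in cluster 7 and of the spike-in scores of clusters 4 and 6 were chosen only after the result was seen, as were the correlations above. Cluster 7, with lysosomal and complement genes, held 30 cells of untrained sample 2 and 4 cells of all other samples. Doublets with a T cell should have positive T cell markers, and 0 of the 30 cells had a mean T cell marker score above 0 (median -0.468, against 0.464 in the T cell-like cells of that sample, 79.5% of which lay above 0). The test was chosen after cluster 7 was seen to have a negative mean of these markers (-0.462), and the T cell-like clusters were defined by them. Its outcome was thus largely known in advance, and it does not decide on doublets. A run of neighbouring wells filled through another gate stays open as a candidate explanation. Pairs were counted between deposited cells next to each other in the order of well numbers, with wells without a deposited cell skipped. The cells made 9 such pairs where random placement gave a mean of 4.57 (one-sided permutation p = 0.02 over 10000 placements, not adjusted, with p of 0.126 to 1 for the other clusters). Their well numbers spanned 80.3% of the sample's span. Skipped wells could lie within a pair, and no label states that cell names number the wells in order. These pairs may therefore not be neighbours on the plate. The fixed lists measured 1 gene of microglia and 3 of macrophages or monocytes, too few to test a source among cells that the sort on CD45 and CD3 would remove, and no biological explanation was tested for a cluster with 0 of 144 cells in untrained sample 1.

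Clusters 4 and 6 had high scores of the same noncoding RNAs, and wells with little cell RNA could give such a pattern. For cluster 6 the spike-in scores lay below those of T cell-like cells by a mean difference of -0.381 (SD 0.071 over samples), higher in 0 of 5 samples. The normalisation is not given, so a low spike-in score need not mean more cell RNA. Every fixed gene list also had a negative mean score in cluster 6, among them ribosomal protein (-0.699) and mitochondrially encoded genes (-0.639). The spike-in scores therefore cannot decide for cluster 6. For cluster 4 little cell RNA stays open too, since the spike-in scores were higher in 5 of 5 samples by a mean of 0.224 (SD 0.126). Cluster 5 had a higher mean spike-in score with the cells of all samples pooled (0.345, against 0.214 in cluster 4), and scores of 0.157 for A630089N07Rik and 0.129 for Kcnq1ot1. Its spike-in score was not compared within samples, so this does not decide on cluster 4. No biological explanation was tested for either cluster.

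The training differences with small p in CD8-gated cells were mostly on the higher side. With scores divided by their SD, 92.5% of such genes were higher. Dividing by an SD keeps the sign of each sample's mean. Genes with untrained samples below 0 and trained samples above 0 therefore keep their direction whatever the spread. The outcome was thus partly fixed, and samples that differ in the spread of their scores stay open as a cause. A larger share of T cell-like cells among the gated cells of trained samples stays open, since the median difference over all genes was 0.008 with gated T cell-like cells only, against 0.046 with all gated cells, and 48.2% of small p were then higher, against 87.7%. A gate at 0.25 gave 0.015 and 48.2%. Training itself stays open as an untested explanation.

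The 5 genes that differed between CD8-gated and CD4-gated cells were set against swaps of the class labels within samples. Of 16 swaps, 1 gave as many genes, the real one, with 5 genes, and the highest of the others gave 0. These swaps are too few for a share under 0.05.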
